A study of Drosophila melanogaster with 42 samples.

How the data were processed

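RNA from the larval ring gland of Drosophila melanogaster, the endocrine organ that makes ecdysone, was measured on one-colour Cy3 NimbleGen arrays. In the wild-type part, ring glands dissected from w1118 larvae and whole w1118 larvae were taken at 4, 8, 24 and 36 h into the third instar, which gives 24 arrays in 8 groups. In the driver-cross part, ring glands were taken 18 and 8 h before puparium formation from larvae of phantom-Gal4 crossed to w1118 (control), to RasV12, a constitutively active Ras, or to a torso-RNAi transgene, which gives 18 arrays in 6 groups. Each group had 3 arrays, which the labels call biological replicates. For all 9 arrays of the 8 h groups the sample title gives 18 h and the source description 8 h, so every 8 h result rests on the choice between them. The source description was used, since it gives the times that the design text names, and the titles call the gut blue in the 18 h groups and partly clear in the 8 h groups.

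The deposited values are intensity values on a linear scale, made by the authors with RMA per the submitters' processing notes, which give no version. The probe annotation, the background correction and the slide each array lay on are not given in the sources used here. The table held 16637 FlyBase transcript identifiers in a row each, with no missing value. The lowest intensity of an array lay between 8.23 and 9.52 in the wild-type part and between 1.83 and 2.06 in the driver crosses, and the values had different numbers of decimals, so the parts were taken as normalized separately. No test was made across the parts. Array medians ranged from 276.1 to 335.5 and from 348.8 to 393.6. Replicate arrays correlated with r between 0.9742 and 0.999 across transcripts, which are not independent, and 0 columns were identical. The number of arrays limits the precision.

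The files do not pair the identifiers with gene names. A reference gene table of the Release 6 plus ISO1 MT assembly held 44 of the identifiers among its synonyms. Of these, 16 belonged to 1 gene and were named, and 28 belonged to several genes and were left unnamed. The 30 gene lists fixed before the data were examined had 0 measured members among the named transcripts, so their tests, the levels of the manipulated genes and the scaling on ribosomal protein genes were not run. The rule for named genes, also fixed then, was to take from each main comparison the 6 transcripts with the largest rise and the 6 with the largest fall among those with an adjusted p under 0.05 and no overlap between the sides. Since the identifiers carry no names, 2 of each are printed. The 16 named transcripts are described because they had a name, whatever their values.

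All values were taken to log2 without a pseudocount. Each part was fitted with limma 3.58.1 in R 4.3.3, with group means, planned contrasts and empirical Bayes moderation without trend or robust options, and p-values were adjusted by the Benjamini-Hochberg method over 16637 transcripts within each of 17 contrasts. A transcript was called at an adjusted p under 0.05, 2-sided. Errors of log2 changes are limma standard errors, and levels are means of intensities with their SD. After the data were examined, 4 transcript sets were defined in the wild-type part and tested in the driver crosses. These were transcripts at least 4-fold higher, or at least 4-fold lower, in ring gland than in whole larva at all 4 times, and transcripts that rose, or fell, at least 2-fold in the ring gland from 4 to 36 h, all at an adjusted p under 0.05. The sets were tested with camera at a preset correlation of 0.01, adjusted over 20 tests, again with an estimated correlation, with fry, and against 10000 random lists matched on mean intensity. Comparisons that shared control or 4 h arrays were set beside 100 simulations of unchanged groups. With 3 control arrays a time, the controls could not be split into parts of 2.

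The calling step was tested on simulated data with 16637 transcripts, of which 50 were changed at each fold size. For ring gland at 36 against 4 h, it recovered 40% of the 1.5-fold, 70% of the 2-fold and 96% of the 4-fold changes, with 7 false calls. For RasV12 against control at 18 h, it recovered 36%, 66% and 82%, with 10 false calls. The set test, simulated for torso-RNAi against control at 18 h, found a shift of 0.3 in 300 transcripts in 20 of 20 data sets and called an unshifted set in 0 of 20. Those transcripts were drawn independently, so the simulation could not show false calls from correlation within a set. The estimated correlations of the 4 real sets lay between 0.034 and 0.128.

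Alternatives planned before the data were examined were a second quantile normalization, a filter on dim transcripts, trend and robust moderation, array weights, a fit on the compared groups alone, the replicate number as a block, the removal of each array in turn and a 2-fold minimum. Centring each array on its median deviation from the mean array, and leaving out 3 doubted wild-type arrays, were added after seeing the data. The doubted arrays were replicate 1 of whole larva at 24 h and at 36 h, which deviated most from their groups in the wild-type part, and replicate 1 of ring gland at 36 h, which was shifted as a whole.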

Results

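The 42 arrays address how the ring gland differs from the rest of the larva and changes through the last instar, and how its transcripts respond when signalling through the receptor Torso and Ras is altered in the gland. The wild-type part had 24 arrays and the driver-cross part 18, with 3 in each group. Values are RMA intensities of 16637 transcripts.

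Most transcripts differed between ring gland and whole larva, averaged over the 4 times. Fatp1 (FBtr0080133), which encodes a fatty acid transport protein, was higher in ring gland by a log2 change of 1.55 ± 0.09 (SE, adjusted p = 4e-12). At 36 h its intensity was 3120 ± 342 (SD, n = 3) in ring gland and 602 ± 128 (SD, n = 3) in whole larva. The nucleolar protein transcript sle (FBtr0082231) was higher by 1.24 ± 0.06 and kis (FBtr0078144), a chromodomain protein of the trithorax group, by 1.23 ± 0.11. Transcripts of the GATOR2 subunits mio and Wdr24 were higher by 0.93 ± 0.07 and 0.96 ± 0.09. CG31178 (FBtr0084138) was lower in ring gland at 24 and 36 h, by log2 changes of -2.63 and -4.55, and was not called at 4 h (-0.45, adjusted p = 0.55) or 8 h (-1.06, adjusted p = 0.14). Without replicate 1 of whole larva at 24 h the first was -3.64, and without replicate 1 at 36 h the second was -3.85.

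Of the 16 named transcripts, 11 were called higher in ring gland over the mean of the times, 2 lower and 3 neither way, and 13 were called when adjusted over the list alone. The 3 were called at single times. NaPi-III was higher at 4 h (0.74) and lower at 24 and 36 h (-0.48 and -0.52). The rdx transcript was higher at 4 h (0.39) and lower at 36 h (-0.47), and alpha-Spec was lower at 8 h (-0.44). The largest differences belonged to transcripts without a name. FBtr0088009 had an intensity of 9750 ± 1220 (SD, n = 12) in ring gland and 66.8 ± 14.2 (SD, n = 12) in whole larva, and FBtr0113450 was 126-fold higher. FBtr0075443 was 436-fold lower in ring gland, at 16.3 ± 3 against 7150 ± 1570, and FBtr0071542 was 393-fold lower. In total 9492 transcripts were called higher and 4758 lower. At 4, 8, 24 and 36 h the called numbers were 10224, 10776, 11530 and 13429. With arrays centred, the share called higher at these times went from 66.3, 66.9, 66.5 and 69.7% to 51.8, 51.7, 51 and 49.9%. At all 4 times 5365 transcripts were called higher and 2095 lower, and 260 and 944 of these were at least 4-fold higher or lower throughout. The median transcript lay 0.27 higher in ring gland on the log2 scale. With arrays centred, 6586 were called higher and 6911 lower, and His4r, a replacement histone H4 transcript, lost its call, at a log2 change of 0 against 0.3 ± 0.04.

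**Figure D1:**
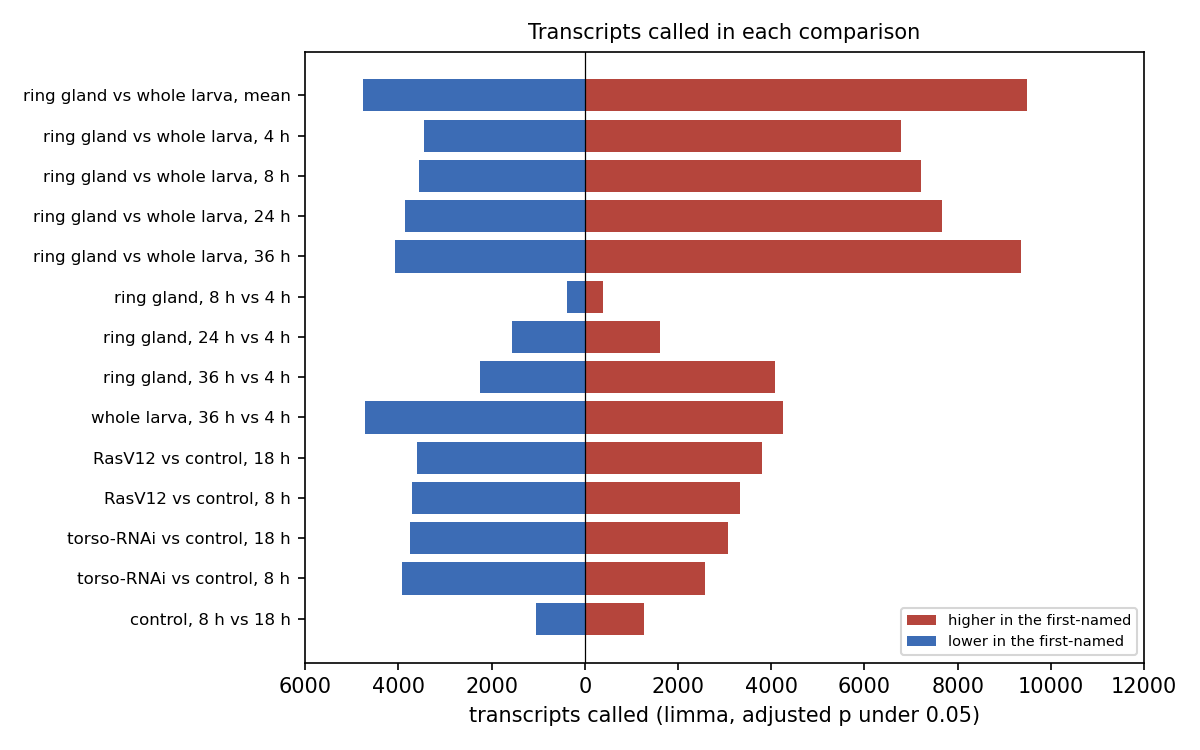
Bars give the number of transcripts called by limma at an adjusted p under 0.05, higher to the right and lower to the left of 0, for 14 comparisons. Ring gland against whole larva gave 14250 calls over the mean of the times, and ring gland at 8 against 4 h gave 790.

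Within the wild-type ring gland, the change from the 4 h level was larger at later times. NaPi-III (FBtr0076213) fell by 1.34 on the log2 scale from 4 to 36 h (SE 0.2, adjusted p = 3.7e-05), from an intensity of 1790 ± 408 to 703 ± 132 (SD, n = 3 each). Fatp1 fell from 6870 ± 612 to 3120 ± 342, a log2 change of -1.14 ± 0.17. The transcripts of sle and rdx, an adaptor of Cul3 ubiquitin ligases, fell by 0.72 (SE 0.12) and 0.62 (SE 0.09). CG16974 rose by 0.72 ± 0.17 (adjusted p = 0.0031), from 1150 ± 89.4 to 1920 ± 416.

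Of the 16 named transcripts, 2 rose, 5 fell and 9 were not called at 36 against 4 h, and 8 were called when adjusted over the list alone. His4r was among those that rose, and alpha-Spec, the spectrin of the membrane cytoskeleton, among those that fell. The rise of His4r was not called with arrays centred, at 0.17. The largest rise was that of FBtr0083461, from 16.2 ± 0.331 to 6840 ± 3280 (SD, n = 3 each), followed by FBtr0077578 at 195-fold. In whole larva FBtr0083461 rose from 218 ± 200 to 31800 ± 3650, so its level at 36 h was higher there than in ring gland. FBtr0077022 fell from 6800 ± 1400 to 32.5 ± 1.95 and FBtr0078452 from 11900 ± 341 to 80.2 ± 13.8. At 8, 24 and 36 h against 4 h, 790, 3184 and 6314 transcripts were called. Of the 4077 called higher at 36 h, 1345 were also called higher at 24 h and 272 at 8 h. Of the 2237 called lower at 36 h, 1282 were also called lower at 24 h and 326 at 8 h. These comparisons share the 4 h arrays, so part of this overlap may come from them. The changes at 8 and 24 h had the sign of the change at 36 h for 70.6 and 79.9% of transcripts, against 66.7% for simulated unchanged groups, and the covariances were 0.221 and 0.512 against 0.038. The count at 8 h was 90 when only the 6 arrays compared were fitted. With arrays centred, the higher and lower calls at 36 h were 2472 and 3116, in place of 4077 and 2237. At 24 h they were 1311 and 1922, in place of 1619 and 1565, and at 8 h 278 and 569, in place of 399 and 391. Among those changed at least 2-fold the lower calls outnumbered the higher, with 66 higher and 198 lower at 8 h, 330 and 696 at 24 h and 873 and 1178 at 36 h.

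**Figure D2:**
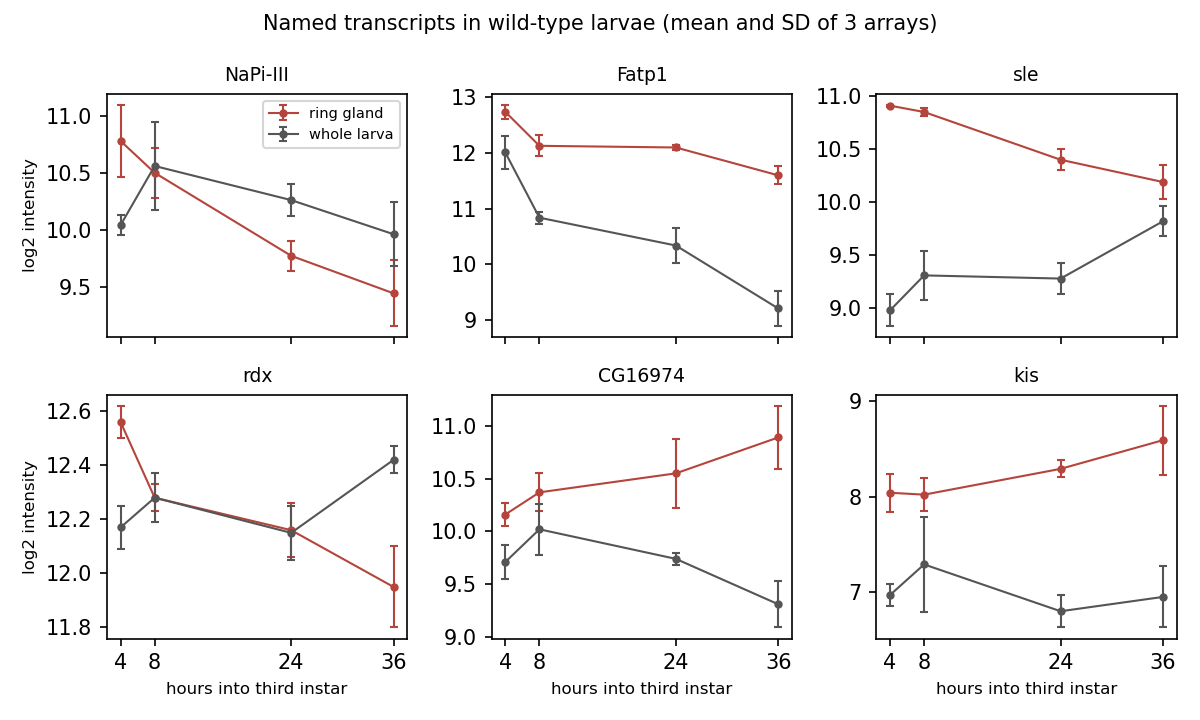
Points are means and bars SDs of the log2 intensity of 3 arrays, against hours into the third instar, for 6 named transcripts in ring gland (red) and whole larva (grey). The sle transcript fell in ring gland and rose in whole larva between 4 and 36 h, by log2 changes of -0.72 and 0.84.

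Whole larvae also changed between 4 and 36 h, and for some transcripts the change differed from that of the gland. Fatp1 fell further in whole larva, by 2.8 (SE 0.17), from an intensity of 4170 ± 868 to 602 ± 128 (SD, n = 3 each). CG31178 rose in whole larva by a log2 change of 4.26 ± 0.62 (adjusted p = 1.4e-05), or 3.56 without replicate 1 at 36 h, with a wide spread at 36 h of 503 ± 459, and was 16.6 ± 2.28 in ring gland at that time. The sle transcript rose in whole larva by 0.84 ± 0.12, and rdx by 0.25 ± 0.09. SuUR, a chromatin protein that limits replication in polytene chromosomes, fell in whole larva by 0.56 (SE 0.17).

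Of the 16 named transcripts, 7 rose in whole larva, 3 fell and 6 were not called. Over all transcripts 4253 rose and 4708 fell, or 4700 and 4287 with arrays centred and 2037 and 1660 at a 2-fold minimum, led by FBtr0077393 and FBtr0083441 among the rises, at 341-fold and 317-fold, and by FBtr0077057 and FBtr0086989 among the falls, at 399-fold and 345-fold. In both tissues 1427 transcripts rose, where independent lists would share 1042, and 1295 fell, where they would share 633. There were 651 that rose in ring gland and fell in whole larva, and 144 with the opposite pattern, where independent lists would share 1154 and 572. The test of the difference itself called 7478 transcripts. For 4603 of them the signed log2 change was more positive in ring gland, which includes smaller falls, as for Fatp1. With arrays centred, these numbers were 6870 and 2961, and at a 2-fold minimum 3984 and 1956.

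RasV12 in the gland was compared with the control cross to see what activated Ras does to the gland's transcripts. NaPi-III was lower in RasV12 glands, at 394 ± 26.1 against 1330 ± 506 (SD, n = 3 each) at 18 h before puparium formation, a log2 change of -1.7 ± 0.19 (adjusted p = 1.1e-05). At 8 h it was -1.71 ± 0.19. The sle transcript was lower by a log2 change of -1.22 ± 0.11 at 18 h and -0.77 ± 0.11 at 8 h, and kis by -1.09 ± 0.12 and -0.72 ± 0.12. LanA, a laminin chain of basement membranes, was lower by -0.58 ± 0.07 and -0.47 ± 0.07.

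Of the 16 named transcripts, 0 were called higher and 9 lower at 18 h, and 2 higher and 10 lower at 8 h. Those higher at 8 h were fend, which acts in motor axon growth, at 0.9 ± 0.26, and rdx at 0.27 ± 0.07. Adjusted over the list alone, 9 and 12 were called. Among all transcripts 3800 were higher and 3602 lower at 18 h (3437 and 3893 with arrays centred), and 3331 were higher and 3706 lower at 8 h. Of those changed at least 2-fold, 815 were higher and 1521 lower at 18 h, and 809 and 1430 at 8 h. FBtr0071716 was 2730 ± 491 in RasV12 glands and 7.03 ± 0.476 in controls at 18 h, and FBtr0076196 was 10400 ± 8910 against 13.1 ± 5.5, with a fold between 115 and 1260 when 1 array was left out, RasV12 replicate 3 moving it most. FBtr0113863 was lower at both times, by 89.4-fold at 18 h and 243-fold at 8 h, and FBtr0077115 was 58.5-fold lower at 18 h. At 8 h, FBtr0076196 was 366-fold higher, and FBtr0071920 was 2450 ± 2340 against 4.77 ± 0.968, with a fold between 74.4 and 745 when 1 array was left out, RasV12 replicate 2 moving it most. FBtr0083389 was lower, at 32.5 ± 30.7 against 5400 ± 4400, with a fold between 67.7 and 335, control replicate 3 moving it most. Between 18 and 8 h, 2225 transcripts were higher at both times and 2442 lower at both. The test of the difference between the times called 1245 transcripts, or 703 without control replicate 3 at 8 h.

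Transcript sets from the wild-type part were set against these changes. The 1178 transcripts that fell with age in the wild-type gland had a median log2 change of -0.42 in RasV12 glands at 18 h, with 113 called higher and 321 lower (camera adjusted p = 0.0021). This call was lost with an estimated correlation (adjusted p = 0.39). The 944 whole-larva-enriched transcripts had a median of -0.31 (adjusted p = 0.025), and that call was lost with an estimated correlation (adjusted p = 0.39). It was also lost with arrays centred (adjusted p = 0.067). At 8 h, 0 of the 4 sets passed at adjusted p values from 0.17 to 0.28, and at an unadjusted camera p under 0.05 the number was 0. Among random lists matched on intensity, the medians of the whole-larva-enriched and rising sets at 8 h, 0.16 and 0.14, lay at percentile 100, and those of the ring-gland-enriched and falling sets at 7.59 and 21.24. Random lists do not carry the correlation between transcripts of a set. Fry, which does not compare a set with other transcripts, called the 260 ring-gland-enriched transcripts at 8 h (adjusted p = 0.015). It did not call the falling, rising or whole-larva-enriched sets at 8 h (adjusted p = 0.082, 0.25 and 0.3). At 18 h it called the falling, whole-larva-enriched and ring-gland-enriched sets (adjusted p = 0.0079, 0.014 and 0.019). The rising set was not called by fry at 18 h (adjusted p = 0.07).

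Torso-RNAi was compared with the same control cross to see how RNAi against the receptor alters the gland's transcripts. The level of torso itself could not be read, for want of names. The kis transcript was lower in torso-RNAi glands, at 573 ± 22.6 against 1530 ± 73.9 (SD, n = 3 each) at 18 h, a log2 change of -1.42 ± 0.12 (adjusted p = 1e-06), and by -1.18 ± 0.12 at 8 h. CG16974 was lower by -1.1 ± 0.08 and -0.87 ± 0.08, SuUR by -0.73 ± 0.07 and -0.62 ± 0.07, and LanA by -0.6 ± 0.07 and -0.8 ± 0.07. The E1 ubiquitin-activating enzyme transcript Uba1 was lower by -0.46 ± 0.07 and -0.45 ± 0.07. NaPi-III was higher at 8 h, by 0.93 ± 0.19 (adjusted p = 0.0015), and its log2 change at 18 h was -0.16 ± 0.19 (adjusted p = 0.55).

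Of the 16 named transcripts, 1 was called higher and 6 lower at 18 h, and 2 higher and 6 lower at 8 h. His4r was higher at both times, by 0.22 ± 0.06 and 0.31 ± 0.06. Adjusted over the list alone, 8 were called at each time. Among all transcripts 3074 were higher and 3754 lower at 18 h (3480 and 3467 with arrays centred), and 2579 were higher and 3926 lower at 8 h. With arrays centred, the calls at 8 h were 3283 higher and 3290 lower. Fitted on the compared arrays alone, 4650 were called at 8 h, in place of 6505. The torso-RNAi arrays at 8 h deviated more from their group mean than the controls. The SDs of their log2 deviations were 0.414 to 0.437, against 0.257 to 0.265 for the 8 h controls. FBtr0082154 was 829-fold higher at 18 h, at 4810 ± 1200 against 6.18 ± 3.18, and FBtr0083330 was 8390 ± 586 against 134.6 ± 224.9, a log2 change of 8.73 ± 2.04 (SE). Its fold lay between 163 and 1900 when 1 array was left out, control replicate 2 moving it most, and the ratio of its mean intensities was 62.3. FBtr0113863 was 614-fold lower and FBtr0078505 was 145-fold lower at 18 h, and at 8 h the former was 459-fold lower and the latter 24.9 ± 14 against 15400 ± 1070. At 8 h, FBtr0080175 was 353-fold higher, and FBtr0086643 was 4220 ± 5930 against 9.42 ± 7.27, with a fold between 96.9 and 439 when 1 array was left out, torso-RNAi replicate 3 moving it most. At both times 1821 transcripts were higher and 2906 lower, and the test of the difference between the times called 500, or 281 without torso-RNAi replicate 2 at 18 h.

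Whole-larva-enriched transcripts were higher in torso-RNAi glands at 18 h. Of the 944, 322 were called higher and 31 lower, with a median log2 change of 0.84 (camera adjusted p = 3.2e-09, and adjusted p = 0.032 with an estimated correlation). Of the 1178 that fell with age in the wild-type gland, 500 were called higher and 64 lower, with a median of 0.88 (adjusted p = 9.9e-13, and 0.036 with an estimated correlation). These sets share 348 members. At 8 h their medians were 0.4 and 0.41, and the camera calls were lost with an estimated correlation (adjusted p = 0.082 and adjusted p = 0.14). The 260 ring-gland-enriched transcripts had medians of -0.27 at 18 h and -0.38 at 8 h, with 108 and 118 called lower, and these calls were lost with an estimated correlation (adjusted p = 0.43 and adjusted p = 0.39). The 873 that rose with age had a median of -0.34 at 18 h (adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation). At 8 h their median was -0.05 (camera adjusted p = 0.75). Fry, which does not compare a set with other transcripts, called all these sets at 18 h (adjusted p from 2.9e-05 to 0.00013). At 8 h it called the ring-gland-enriched, whole-larva-enriched and falling sets (adjusted p = 4.3e-05, 0.0015 and 0.0036). It did not call the rising set at 8 h (adjusted p = 0.12).

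**Figure D3:**
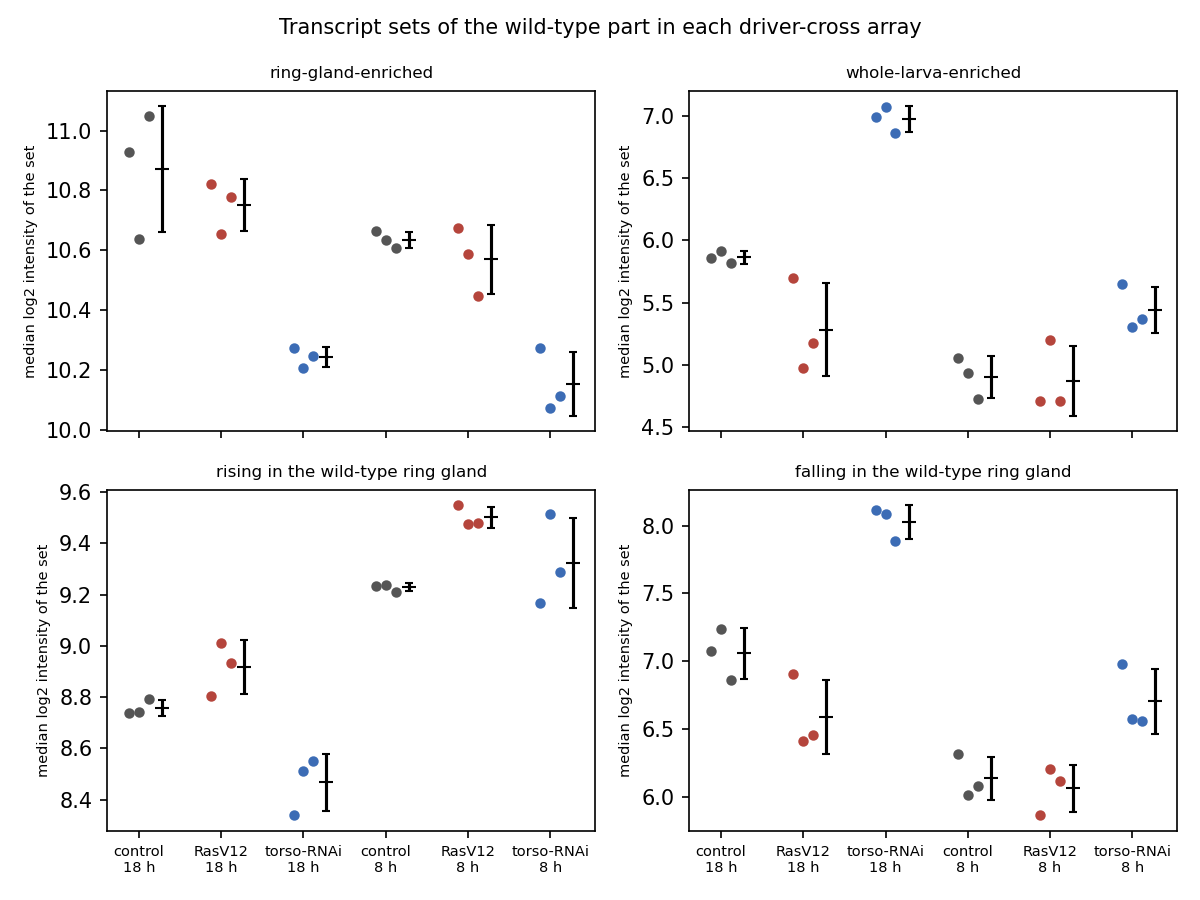
Each dot is the median log2 intensity of a transcript set in 1 array, with the mean and SD of 3 arrays beside it, for control (grey), RasV12 (red) and torso-RNAi (blue) glands at 18 and 8 h before puparium formation. The whole-larva-enriched set had a mean of 6.98 in torso-RNAi and 5.86 in control glands at 18 h.

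RasV12 and torso-RNAi changes were set side by side, since Torso signals through Ras. At 18 h, kis was lower in both genotypes, by log2 changes of -1.09 and -1.42, and LanA, sle, CG16974 and Uba1 were also called lower in both. NaPi-III was called lower in RasV12 glands at both times, at -1.7 and -1.71, and its log2 changes in torso-RNAi glands were -0.16 ± 0.19 (not called) and 0.93 ± 0.19. His4r was lower in RasV12 glands at 18 h, by -0.17 ± 0.06, and higher in torso-RNAi glands. There were 6 transcripts at least 16-fold lower in both genotypes at both times, and 0 at least 16-fold higher.

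At 18 h, 1261 transcripts were called higher and 1572 lower in both, where independent lists would share 702 and 813. A further 553 were higher in RasV12 and lower in torso-RNAi glands, and 513 the reverse, where independent lists would share 857 and 666. This turned at a 2-fold minimum, with 116 and 128 going opposite ways against 51 and 94 for independent lists, beside 111 higher and 205 lower in both against 50 and 95. At 8 h, 913 were higher and 1472 lower in both, where independent lists would share 516 and 875. A further 620 and 527 went opposite ways, where independent lists would share 786 and 574. At a 2-fold minimum 107 were higher and 185 lower in both at 8 h, against 38 and 94. Those that went opposite ways were 121 and 132, against 53 and 68. Across transcripts, which are not independent, the log2 changes correlated with r = 0.18 at 18 h and 0.16 at 8 h. The share of transcripts with the same sign in both was 60.7% at 18 h and 57.6% at 8 h. Simulated unchanged groups gave 0.5 and 66.6%, which the shared control arrays alone produce. Real changes that differ between the genotypes lower both values, so neither can tell agreement from none. The covariance was 0.138 and 0.109 against a simulated 0.056, a difference of 0.081 and 0.052. By this measure the changes varied together more than the shared arrays gave in simulation. Part of the overlap may come from the shared control arrays.

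In the control cross, fewer transcripts were called between 18 and 8 h before puparium formation than in either genotype against control. NaPi-III fell from 1330 ± 506 to 755 ± 32.4 (SD, n = 3 each), a log2 change of -0.76 ± 0.19 (adjusted p = 0.019), and sle fell by 0.4 (SE 0.11, adjusted p = 0.028). Without control replicate 2 at 18 h the NaPi-III change was -0.46. Leaving out that array also gave NaPi-III changes at 18 h of -1.4 in RasV12 and 0.13 in torso-RNAi glands. Its torso-RNAi by time difference was then 0.8. The other 14 named transcripts were not called. FBtr0112492 rose 122-fold and FBtr0078847 rose 36.2-fold, and FBtr0085626 and FBtr0086809 fell 82.5-fold and 55.8-fold. In total 1264 rose and 1040 fell, or 1095 and 1192 with arrays centred and 394 and 511 at a 2-fold minimum.

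Transcripts that fell with age in wild-type glands also fell here, with 335 of 1178 called lower, 20 higher and a median log2 change of -0.66 (camera adjusted p = 7.5e-23, and adjusted p = 0.016 with an estimated correlation). Of the 873 that rose with age, 268 were called higher and 29 lower, with a median of 0.4 (adjusted p = 1.2e-13, and adjusted p = 0.045 with an estimated correlation). The whole-larva-enriched set had a median of -0.47 (adjusted p = 4.4e-11, and adjusted p = 0.024 with an estimated correlation). Without replicate 2 of the control at 8 h, the number of called transcripts fell from 2304 to 1227. With array weights it was 4455.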

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

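The tests of the whole-larva-enriched set, of the control difference and of the splits of interactions below were chosen after those patterns had been seen.

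The change from 4 to 36 h differed between ring gland and whole larva for 7478 transcripts. Named transcripts with this difference, given as the ring gland change minus the whole larva change on the log2 scale, were CG16974 at 1.12, Fatp1 at 1.66, CG31178 at -4.1, sle at -1.56, NaPi-III at -1.26, fend at -0.98, rdx at -0.87 and LanA at -0.5. The RasV12 change differed between 18 and 8 h for 1245 transcripts, with rdx 0.47 higher at 8 h. The torso-RNAi change differed for 500 transcripts, with NaPi-III 1.09 higher at 8 h.

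Other splits of the same arrays were counted for each comparison. Of 100 splits for ring gland against whole larva over the 4 times, 1 called as many as the 14250 seen, the highest other being 11942, so chance can be excluded there. The planned test of the interactions was plain splits, in which 5, 3 and 6 of 100 called at least as many transcripts as seen for the tissue, RasV12 and torso-RNAi differences, the highest others being 9181, 2831 and 2308. The share was thus not under 0.05 for the tissue and torso-RNAi differences. Plain splits carry the effects of tissue, genotype and time themselves, so after these counts had been seen the splits were drawn again with the additive effects of both factors removed. For the tissue by time difference, 2 of 100 then called at least 7478, the highest other being 7653. For RasV12 by time 1 of 100 called at least 1245, the highest other being 1, and for torso-RNAi by time 1 of 100 called at least 500, the highest other being 31. In the later count the share was under 0.05 for all of these differences. That test was chosen after the planned counts had been seen, so it does not by itself exclude chance. The planned splits cannot decide for any of them, since they carry the effects of tissue, genotype and time. That holds for RasV12 too, where another split called 2831 against the real 1245. In the later count for tissue by time, another split called more than the real one. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. The seen count was reached by 1 split each, the real one. The seen and highest other counts at 4, 8, 24 and 36 h for ring gland against whole larva were 10224 and 0, 10776 and 1, 11530 and 1, and 13429 and 2. For the ring gland at 8, 24 and 36 h against 4 h they were 790 and 37, 3184 and 9, and 6314 and 8, and for whole larva at 36 h 8961 and 0. For RasV12 they were 7402 and 0 at 18 h and 7037 and 1 at 8 h, for torso-RNAi 6828 and 5 and 6505 and 1, and for the control times 2304 and 0.

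Whole-larva-enriched transcripts were higher in torso-RNAi glands at 18 h, by a median log2 change of 0.84, and at 8 h by 0.4, where the call was lost with an estimated correlation (adjusted p = 0.082). Tissue carried over in dissection could give this. Of the 100 such transcripts brightest in whole larvae, 73% rose by over 0.5 at 18 h, with a median of 1.49. The 73% decides nothing, since brightness is not comparable between probes. In RasV12 glands at 18 h, 15% of the same 100 rose by over 0.5. The rise was thus not common to both genotypes, which does not tell carried-over tissue from a younger gland. The 596 that did not fall 2-fold with age had a median of 0.55 (quartiles -0.06 and 1.47). A younger gland could also give the rise of the set. In the earlier of its tests the 830 transcripts that fell with age and were not whole-larva-enriched had a median of 0.67, but tissue from outside the gland can carry these too. In the narrower test that replaced it, the 102 that fell with age and were called higher in ring gland than in whole larva at all 4 times had a median of 0.13 at 18 h (29 called higher, 26 lower), between the bounds of 0.3 and 0.1, and -0.25 at 8 h (quartiles -0.63 and 0.41, 22 higher, 32 lower), so its members went both ways. Both explanations stay open, and an effect of torso itself was not tested.

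The 6 transcripts at least 16-fold lower in both genotypes at both times share their control arrays at each time. The 18 and 8 h controls differed by a median of 0.11 on the log2 scale at these transcripts, which decides little, since the choice needs both to be high, so transcripts were also chosen at 1 time alone and read in the control arrays of the other. The 7 chosen at 18 h had a median drop of -0.03 there and the 8 chosen at 8 h a median drop of 0.15 (1 of them over 2), which argues against a chance deviation of the control arrays as the cause for most of them. The genetic background of the crosses stays open. In w1118 ring glands 66.7% of the 6 lay above the median of all transcripts at every time, which decides nothing, since brightness is not comparable between probes. An effect common to both transgenes also stays open as untested.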

How the results depend on the processing

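Of the alternatives, those added after seeing the data were array centring, leaving out 3 doubted arrays, and every setting of the transcript sets and of the 16-fold count. With a 2-fold minimum the called counts fell by construction. They were 5978, 5087, 5595, 6056 and 7508 for ring gland against whole larva (mean, 4, 8, 24 and 36 h), 264, 1026 and 2051 for ring gland at 8, 24 and 36 h, 3697 for whole larva, 3984 for tissue by time, 2336 and 2239 for RasV12, 2073 and 1886 for torso-RNAi, 905 for the control times and 487 for RasV12 by time. Overlaps at 2-fold were 316 in the same and 244 in opposite directions at 18 h, and 292 and 253 at 8 h. Array weights gave 4455 for the control times, 1995 for RasV12 by time and 773 for torso-RNAi by time. Ring gland at 8 against 4 h gave 90 calls with only its own arrays, which leaves fewer arrays for the spread, and 1192 without the doubted arrays. The cause of the other moves was not tested.

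Leaving out arrays moved 4 counts by over 1.5 times. Ring gland at 8 against 4 h ranged from 399 to 570, with 399 without replicate 1 at 4 h and 493, 481 and 404 without replicates 1, 2 and 3 at 8 h. The control times ranged from 1227 to 1969, with 1299 without replicate 1 at 18 h and 1354 and 1227 without replicates 1 and 2 at 8 h. RasV12 by time ranged from 703 to 1436, with 726 without control replicate 2 at 18 h, 703 without control replicate 3 at 8 h and 815 without RasV12 replicate 1 at 8 h. Torso-RNAi by time ranged from 281 to 647, with 323, 312 and 315 without control replicates 1, 2 and 3 at 18 h, 294 and 295 without control replicates 1 and 2 at 8 h, and 300 and 281 without torso-RNAi replicates 1 and 2 at 18 h. The 16-fold count was 6 or 7. Of the named transcripts, CG31178 alone moved by over 1.5 times in any comparison, its tissue by time difference going from -4.1 to -3.39 without replicate 1 of whole larva at 36 h.

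In RasV12 glands at 18 h, the whole-larva-enriched set lost its call when quantile normalized again (-0.2), centred (-0.35), with an estimated correlation (-0.31), and without control replicate 2 (-0.29) or RasV12 replicate 2 (-0.21), over a range of -0.39 to -0.21. The ring-gland-enriched set gained a call there with array weights (-0.07), and without control replicate 2 (-0.1) or RasV12 replicate 3 (-0.07), over -0.1 to -0.01. In the control times it gained one with array weights (-0.03), and without replicate 2 at 18 h (-0.06) or replicate 1 at 8 h (-0.03), over -0.06 to 0.01. An estimated correlation also ended the calls of medians -0.42, -0.27, -0.34, -0.38, 0.4 and 0.41 given above.

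The replicate number as a block changed no set call and moved no count by over 1.5 times, with 14216 calls for ring gland against whole larva, 650 for ring gland at 8 h, 6184 at 36 h, 7328 and 7037 for RasV12, 6799 and 6513 for torso-RNAi and 2298 for the control times. Arrays with the same number did not deviate together, with a mean correlation of -0.015 in the wild-type part and 0.006 in the driver crosses, and 4 of 24 and 5 of 18 arrays correlated best with their own number. Of 2155 values of named transcripts under the alternatives, 2077 kept their side of the threshold, 46 lost a call, 32 gained one and 0 reversed. Scaling on ribosomal protein genes and the fixed lists were not run for want of names, and separate features were not run since each transcript has a single value. Signal over background is not given, so folds of dim transcripts depend on the authors' background step.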

Other observations

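Age-related transcripts of the wild-type gland were also followed in the driver crosses by their calls. Of the transcripts called higher in the wild-type ring gland at 36 against 4 h, 1184 were called lower in torso-RNAi glands at 18 h, where independent lists would share 920, and 891 were called higher, where they would share 753. Of those called lower with age, 778 were called higher in torso-RNAi glands, against 413 for independent lists, and 303 lower, against 505. In RasV12 glands at 18 h, 1595 of the transcripts called higher with age were called higher and 721 lower, against 931 and 883, and of those called lower with age 736 were called lower and 255 higher, against 484 and 511. The set of 873 that rose at least 2-fold with age had a median of 0.2 there and was not called (camera adjusted p = 0.28, and adjusted p = 0.7 with an estimated correlation), though its median lay at percentile 100 among random lists matched on intensity. Among the named transcripts, Fatp1 and NaPi-III fell at least 2-fold with age. Their log2 changes in torso-RNAi glands at 18 h were -0.16 ± 0.16 and -0.16 ± 0.19, and neither was called. The parts were taken as normalized separately, and these overlaps were counted and not tested.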
